A study of Mus musculus with 4 samples.

How the data were processed

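The data were 2 lists of N6-methyladenosine (m6A) peaks from mouse pancreatic islets, one per genotype. MeRIP-seq fragments RNA, enriches the fragments that an m6A antibody binds (IP) and sequences them beside the unenriched RNA (input). Per the labels, control islets came from mice with a floxed Wtap gene, and knockout islets from mice lacking Wtap in beta cells, all 7 weeks old. Per the labels, 2 ug of RNA was pooled from 10 control mice and from 19 knockout mice, and cut to about 100 nt. Antibody incubation lasted 2 hours at 4 °C, and paired reads were 150 bp long, per the labels. The 4 samples were therefore 1 IP and 1 input library per genotype, and each list was assigned to its genotype by the name it shares with the sample titles.

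The authors trimmed and aligned reads with tools that the submitters' processing notes name as fastp 0.19.11 and BWA 0.7.12, on GRCm38 (mm10). Per the labels, the authors called peaks with exomePeak 2.16.0, each IP against the input of its own genotype, at a q threshold of 0.05; HOMER 4.9.1 was used for motifs. The annotation release and the read depth were not given in the sources used here. Each deposited peak has a p-value, and the log10 of its p and of its q, which the deposited files hold as unbounded score columns. The deposited fold enrichment is the caller's ratio of IP over input in the peak. Fold and q are the authors' own values and were used to describe, rank and filter peaks within a list. The best q was also compared between the lists for genes with peaks in both, and some named genes have values of both lists side by side. The logarithm of the deposited p-value matched its log column within 0.02. A q of 0 was given for 13 control and 15 knockout peaks, which were ranked as the lowest q. No peak of the 2 lists was left out, and peaks without a gene name (742 control and 714 knockout) entered all counts except those of named genes.

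Peaks of the 2 lists were called shared when their exon blocks overlapped by at least 1 bp on the same strand. Genes were compared by identifier as having a peak in both lists, in the control list or in the knockout list. Shares have exact Clopper-Pearson 95% intervals, which cover counting error over peaks or genes and not variation between animals or libraries. Coordinates were taken as 0-based starts, as in the BED format, and are given 1-based on GRCm38. Distances to gene ends used RefSeq gene spans of GRCm38.p6, matched by gene name for 9965 control and 8473 knockout peaks. Transcript regions and sequence motifs need an exon annotation and a genome sequence and were not analysed here.

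The 21 gene lists (351 genes) were fixed before the data were examined. They cover beta cell transcription factors, beta cell function, excitation and exocytosis, insulin signalling, the m6A machinery, other islet and pancreatic cell types, and general processes. For each list, the share of control-peak genes without a knockout peak was set against 10000 random gene sets of the same size. These sets were matched on the number of control peaks (5 or more pooled) and on terciles of the strongest control fold. A list was called outside the random sets below the 2.5th or above the 97.5th percentile, as a description of these libraries. The reverse comparison, from the knockout list, and the comparisons of position and of exon junctions were added after the data were seen. So was a count, in genes with peaks in both lists, of those whose best deposited −log10 q was lower in the knockout list, set against 10000 random sets matched on 20 equal bins of the best control q. It compares genes with other genes of the same pair of lists and is no measure of m6A level.

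Named genes followed a rule fixed in advance. It took every m6A machinery gene with a peak, and from each other list, by strongest fold, up to 4 genes with a control peak alone, 3 with peaks in both lists and 2 with a knockout peak alone. Over all genes it took the 10 strongest by fold in each list among the 50% of peaks with the lower q, where the other list had no peak, and the 5 strongest shared genes. Clone-named genes, pseudogenes and mitochondrial genes were skipped there. Ins2, Cpe, Krt7, Nfkbia, Pak3 and Slfn9 lie outside the rule and were named after their values were seen; other such genes are marked where they appear. Some genes that the rule names are not reported here.

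Alternatives were a q of 0.001 or less, a fold of at least 2, merging of overlapping peaks, a 50% reciprocal overlap, a 200 bp neighbourhood, equal numbers of peaks, unmatched random sets and q-matched random sets. The code was tested on simulated data. It gave 0 wrong overlaps in 40000 simulated pairs. Over the 6250 control-peak genes, 3.0% of 200 unchanged lists of 20 genes fell outside the random sets, and 97.5% of lists with 40 points of added loss lay above them. Over the 5378 knockout-peak genes these shares were 3.5% and 96.5%, and for the count by q over 4137 genes they were 4.5% and 97.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.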

Results

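The m6A landscape of mouse islets was described by 10964 peaks in 6250 genes in control islets and 9411 peaks in 5378 genes in islets lacking Wtap in beta cells. WTAP is a subunit of the complex that writes m6A on mRNA, and the comparison addresses which islet transcripts carry WTAP-dependent m6A. Each genotype was represented by 1 RNA pool with 1 IP and 1 input library, so there were no replicates and no test between genotypes was possible. Read depth is unknown, and all intervals cover counting error only.

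Wtap itself (ENSMUSG00000060475) had peaks in both lists at different places. The control list held 2 peaks on chromosome 17, minus strand, at 12967723 to 12968051 with a fold enrichment of 3.16 and at 12974891 to 12975100 with a fold of 23.2. The knockout list held 1 Wtap peak at 12969434 to 12972739, made of 2 exon blocks, with a fold of 3.37. None of these peaks overlapped. The −log10 q was 3.76 and 4.45 for the control peaks, in that order, and 6.38 for the knockout peak. High folds of the control list repeat on whole multiples of a single step, 1.05, and the fold of 23.2 is on such a multiple. The labels do not say which exons were floxed, so the Wtap peaks do not check the genotype of the pools.

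**Figure D1:**
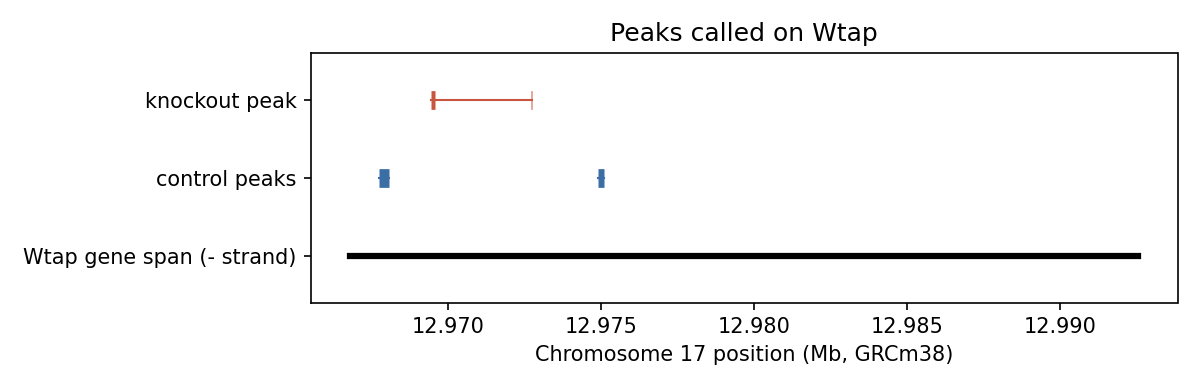
Peaks called on Wtap along chromosome 17 (position in Mb, GRCm38), with the RefSeq gene span in black, control peaks in blue and the knockout peak in red. Thick bars are exon blocks and the thin line joins the 2 blocks of the knockout peak, which lies between the 2 control peaks.

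Among 21 genes of the m6A machinery, 12 had peaks in both lists, 2 had a control peak and no knockout peak, and 3 had a knockout peak and no control peak. The writer subunits Virma, Rbm15, Rbm15b, Zc3h13 and Cbll1 and the demethylases Alkbh5 and Fto were among those with peaks in both. Of the 12, 9 had an overlapping pair, and Wtap and Fto were among the 3 that had none. Ythdf1, a cytoplasmic m6A reader, had 3 control peaks with folds up to 7.02, and Igf2bp2, an RNA-binding protein, had 2 with folds up to 11.6, and neither had a knockout peak. Mettl3, the catalytic writer subunit, had 1 knockout peak with a fold of 8.15 and no control peak. Mettl16 (fold 6.36) and Hnrnpc (4.89) also had 1 knockout peak each and no control peak. The best −log10 q was 7.63 for Ythdf1, 2.65 for Igf2bp2, 2.54 for Mettl3, 7.61 for Mettl16 and 8.3 for Hnrnpc. The folds of 11.6 (Igf2bp2) and 8.15 (Mettl3) lay on the repeated steps of their lists, 1.05 in the control and 0.816 in the knockout. The share without a knockout peak lay at percentile 31.6 of matched random sets. Of the 12 genes with peaks in both, 4 had a lower best −log10 q in the knockout (percentile 1.83 of sets matched on control q).

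Fewer peaks were listed in the knockout, at 0.858 times the control number, and fewer genes, at 0.860 times. Genes with a peak in both lists numbered 4137, against 2113 with a control peak alone and 1241 with a knockout peak alone. The 2113 genes were 33.8% of control-peak genes (interval 32.6 to 35.0), and the 1241 were 23.1% of knockout-peak genes (22.0 to 24.2). With equal numbers of peaks taken from each list, these shares were 29.8% and 27.6%. Summed exonic peak length was 3316990 nt in the control and 2595930 nt in the knockout list, with median peak lengths of 211 and 210 nt.

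Genes with many peaks were rarely without a counterpart. Of control-peak genes with 1 peak, 45.7% (44.1 to 47.3) had no knockout peak, against 4.89% (3.19 to 7.14) of those with 4 or more. In the knockout list the same shares were 33.6% (32.0 to 35.2) and 0.466% (0.0565 to 1.67). Among named genes, 24 had at least 4 control peaks and no knockout peak, and 2, Pak3 and Slfn9, had at least 4 knockout peaks and no control peak. Examples, chosen after their values were seen, were Col6a6, a collagen gene, with 6 control peaks, Flrt1 with 5, and Hcn4, a pacemaker channel gene, with 4.

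Peaks with high deposited folds and no counterpart were found in both lists. Tigar, a regulator of glycolysis, had the highest control fold among genes without a knockout peak, 47.4 at chromosome 6, 127087784 to 127088114. Rusc2 had a fold of 43.2 and the amino acid transporter gene Slc36a4 one of 34.8. Dll4, a Notch ligand, and Ccm2 each had a fold of 30.5. In the knockout list, Fbxo30 led the genes without a control peak with a fold of 28.5, followed by Kitl, which encodes the ligand of the Kit receptor, and the delta cell transcription factor gene Hhex, both at 27.7. All 10 genes named by this rule in each list had folds on whole multiples of a single step per list, 1.05 in the control and 0.816 in the knockout. The read counts behind these folds are unknown, so their order is that of the deposited values alone. Trim44 had the highest control fold of any gene with an overlapping knockout peak, 62.1, followed by Pld1 at 37.9. This order has the same limit, as 98.9% of control peaks with a fold of at least 20 lay on the repeated step.

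At the level of single peaks, 5658 control peaks (51.6%, 50.7 to 52.5) overlapped a knockout peak and 5793 knockout peaks (61.6%, 60.6 to 62.5) overlapped a control peak. Of the 4137 genes with peaks in both lists, 3590 (86.8%, 85.7 to 87.8) had at least 1 overlapping pair. Pclo, a gene of the presynaptic active zone, had 11 control and 12 knockout peaks. The share without a counterpart followed q, from 12.2% (10.9 to 13.7) in the fifth of control peaks with the lowest q to 76.9% (75.1 to 78.7) in the fifth with the highest. The corresponding knockout shares were 6.32% (5.27 to 7.52) and 65.6% (63.4 to 67.7).

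**Figure D2:**
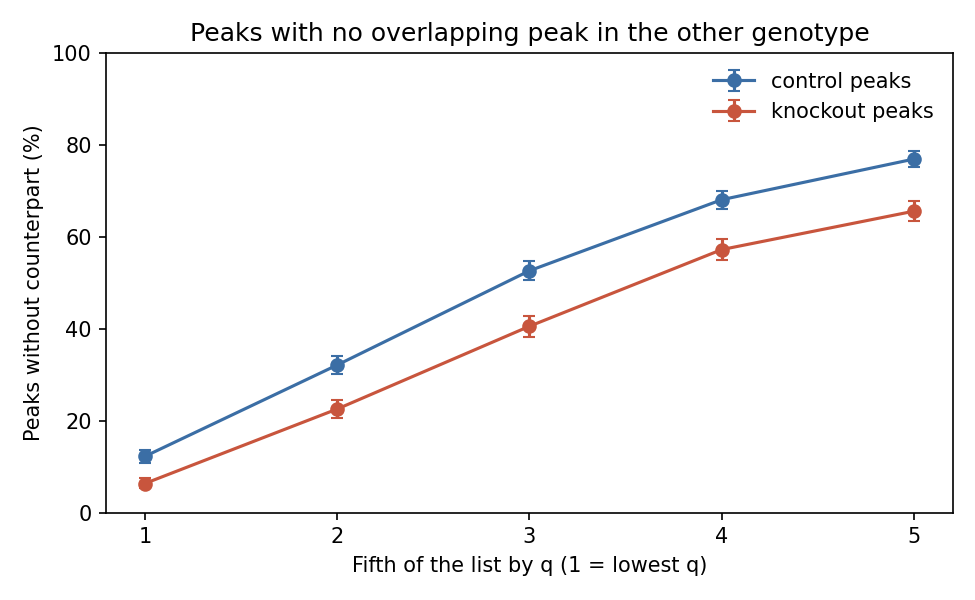
Percent of peaks with no overlapping peak in the other genotype (vertical axis) in 5 equal parts of each list ordered by q (horizontal axis, 1 the lowest q), with exact 95% intervals. Both lines climb, the control line from 12.2% to 76.9% and the knockout line from 6.32% to 65.6%.

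Over all peaks, fold enrichment and q ordered shared and unshared peaks in opposite ways. The median control fold was 3.67 for shared and 4.45 for unshared peaks, and the median knockout fold was 3.31 and 3.75. With peaks of fold 8 or more on the repeated steps left out, these medians were 3.55 and 3.69 in the control and 3.26 and 3.19 in the knockout. The median −log10 q was 7.67 for shared and 3.38 for unshared control peaks, and 6.40 and 3.22 in the knockout list. Shared peaks were longer, with medians of 300 and 180.5 nt in the control list and 269 and 179 nt in the knockout list.

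Most beta cell transcription factor genes had a peak in both genotypes, though not always at the same place. Of 21 with a control peak, 20 also had a knockout peak, and Rfx3, with a fold of 2.45, did not. Of the 20, 16 had at least 1 overlapping pair and 4 had none. Among the 4 were Tcf7l2, Hnf4a and Mnx1, each with 1 peak per list at different places. These were weak calls, with −log10 q of 3.61, 3.36 and 2.22 in the control and 2.62, 1.84 and 2.99 in the knockout. Medians over all peaks were 4.72 and 4.63. Their folds (16.9, 15.8 and 7.37, and 15.5, 12.2 and 7.34) lay near multiples of the repeated steps. Moved m6A sites cannot be read from them. Of the 49 control peaks of this list, 16 (32.7%) had no counterpart. The best −log10 q was lower in the knockout list for 16 of the 20 genes (80.0%), among them, chosen after their values were seen, Neurod1 (265 in the control and 43.1 in the knockout), Mafa (125 and 27.8), Pdx1 (69.4 and 22.0) and Nkx6-1 (61.9 and 13.5). This count lay at percentile 85.1 of sets matched on control q, and 82.5% of all genes in the fifth with the lowest control q had a lower value in the knockout. The value of q depends on read depth and RNA level as well as on m6A. By strongest fold, control then knockout, Neurod1 had 3.45 and 2.99, Pdx1 5.55 and 3.33, and Nkx6-1 3.87 and 2.85. Mafa went the other way, with 3.3 and 18.7, though 18.7 lies near a multiple of the repeated knockout step. For Pdx1 and Nkx6-1 the strongest peaks of the control and knockout lists lay at different places, so their folds do not compare the same site. The share of genes without a knockout peak, 4.76%, lay at percentile 0.465 of matched random sets, and no gene of this list had a knockout peak alone (percentile 0.605). With q at or below 0.001 in both lists these percentiles were 17.1 and 2.54. Of 13 immediate early genes with a control peak, including Klf4, Nr4a1 and Jund, all 13 had a knockout peak (percentile 1.05), and Fosl2 had a knockout peak alone. With q-matched random sets the percentile of the immediate early genes was 10.9.

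Genes of beta cell function were split. Of 24 with a peak, 18 had peaks in both lists, including Chgb, Ffar1 and Prlr. The incretin receptor gene Glp1r (fold 1.73) and the cation channel gene Trpm5 (fold 1.72) had a control peak alone. Ins2, Cpe, Scg5 and Sytl4 had no control peak. The knockout fold was 1.09 for Ins2, the lowest of the knockout list, 1.39 for Cpe, 1.48 for Scg5 and 4.80 for Sytl4. The exocytosis genes Rab3a (fold 5.94) and Unc13a (4.39) had control peaks alone, whereas Rph3al (2.41) and Abcc8, the sulfonylurea receptor gene (2.30), had knockout peaks alone. These lists lay at percentiles 11 and 33.1. The 3 beta cell lists together held 6 genes in each direction, and their control-only share of 10.2% lay at percentile 0.580, which became 16.4 with q-matched sets. The genes of the other lists, without those of the 3 beta cell lists, had a control-only share of 15.3% (22 of 144 genes) at percentile 0.290, which became 3.90 with q-matched sets.

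In insulin signalling, 12 genes including Pik3r1, Irs2 and Rptor had peaks in both lists, which overlapped in 11 genes and not in Rptor. Genes with a control peak and none in the knockout included Tsc2 and Pdpk1, with 1 control peak each (percentile 66.2). Of 13 apoptosis and inflammation genes with a control peak, 5 had no knockout peak, namely Bcl2, Casp8, Nfkbia, Socs2 and Tnfaip3, and Bcl2l1 and Socs3 were among the 8 with both (percentile 51.4). Of 21 unfolded protein response genes with a control peak, 19 had both, including Eif2ak3, Dnajb9 and Pdia4, and Edem1 and Pdia6 had control peaks alone (percentile 10.6). Among chromatin regulators 18 had both and Tet1 a control peak alone (percentile 34.3). Circadian clock genes with a control peak alone were Arntl and Bhlhe40, and Cry2 had knockout peaks alone (percentile 39.7). Cell cycle genes had 5 in both and Cdk4 in the control alone (percentile 50). Hk1 had control peaks alone, Neurog3 and Smad3 knockout peaks alone, and Hes1 peaks in both lists, among genes that beta cells normally repress (percentile 62.3). The best −log10 q was 4.18 for Hk1, 1.99 for Neurog3 and 2.83 for Smad3, against medians over all peaks of 4.72 in the control and 4.63 in the knockout. The folds of Hk1 (22.1) and Smad3 (16.3) lay near multiples of the repeated steps.

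Of 37 markers of other cell types with a peak, 23 had peaks in both lists, 9 a knockout peak alone and 5 a control peak alone. The 9 were 28.1% of those with a knockout peak, against 23.1% over all genes, and the 5 were 17.9% of those with a control peak, against 33.8%. The control-only share of these 7 lists together lay at percentile 2.34, which became 3.42 without matching, 7.90 with q-matched sets, 7.07 at a fold of at least 2 and 44.4 in the better 50% of genes by q. Among the 23 with peaks in both lists, the best −log10 q was lower in the knockout for 6 (26.1%), at percentile 0.005 of sets matched on control q, against 38 of 53 genes (71.7%, percentile 30.4) of the 3 beta cell lists. It was lower for 2 of 8 endothelial genes (percentile 0.900), and Esm1 (11.2 in the control and 30.0 in the knockout) and Pecam1 (3.49 and 13.6), chosen after their values were seen, were among those with higher values. The knockout-only markers comprised the alpha cell genes Pou3f4 (fold 13.0) and Ttr (1.27), the delta and PP cell genes Hhex and Rbp4, the acinar gene Try4, the ductal genes Krt7, Sox9 and Spp1, and the immune gene Cd74. By −log10 q the order of the alpha cell genes was the reverse, with 2.21 for Pou3f4 and 23.9 for Ttr. The folds of Pou3f4, Sox9 (17.1) and Hhex (27.7) lay near multiples of the repeated knockout step. The control-only markers included Bhlha15, Tie1, C1qa and C1qb. The percentiles of control-only shares were 10.2 for alpha, 20.5 for delta and PP, 56.5 for acinar, 43.5 for ductal, 8.11 for endothelial, 4.01 for stromal and 88.2 for immune markers. Ribosomal protein genes had 5 in both lists and 6 with knockout peaks alone, including Rpl23 and Rpl7 (percentile 97.8 in the knockout direction, 96.3 with q at or below 0.001, and 5.15 in the control direction). Oxidative phosphorylation had 1 gene with a peak, Uqcrc1, in both lists (percentile 29.1). Of the 21 lists, 2 lay outside the random sets in the control direction and 2 in the knockout direction, where the random sets themselves give 0.497 and 0.433 lists. These figures take listed genes to be like other genes with a peak. All listed genes together had a control-only share of 13.8%, against a median of 23.2% in matched sets (percentile 0.0).

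**Figure D3:**
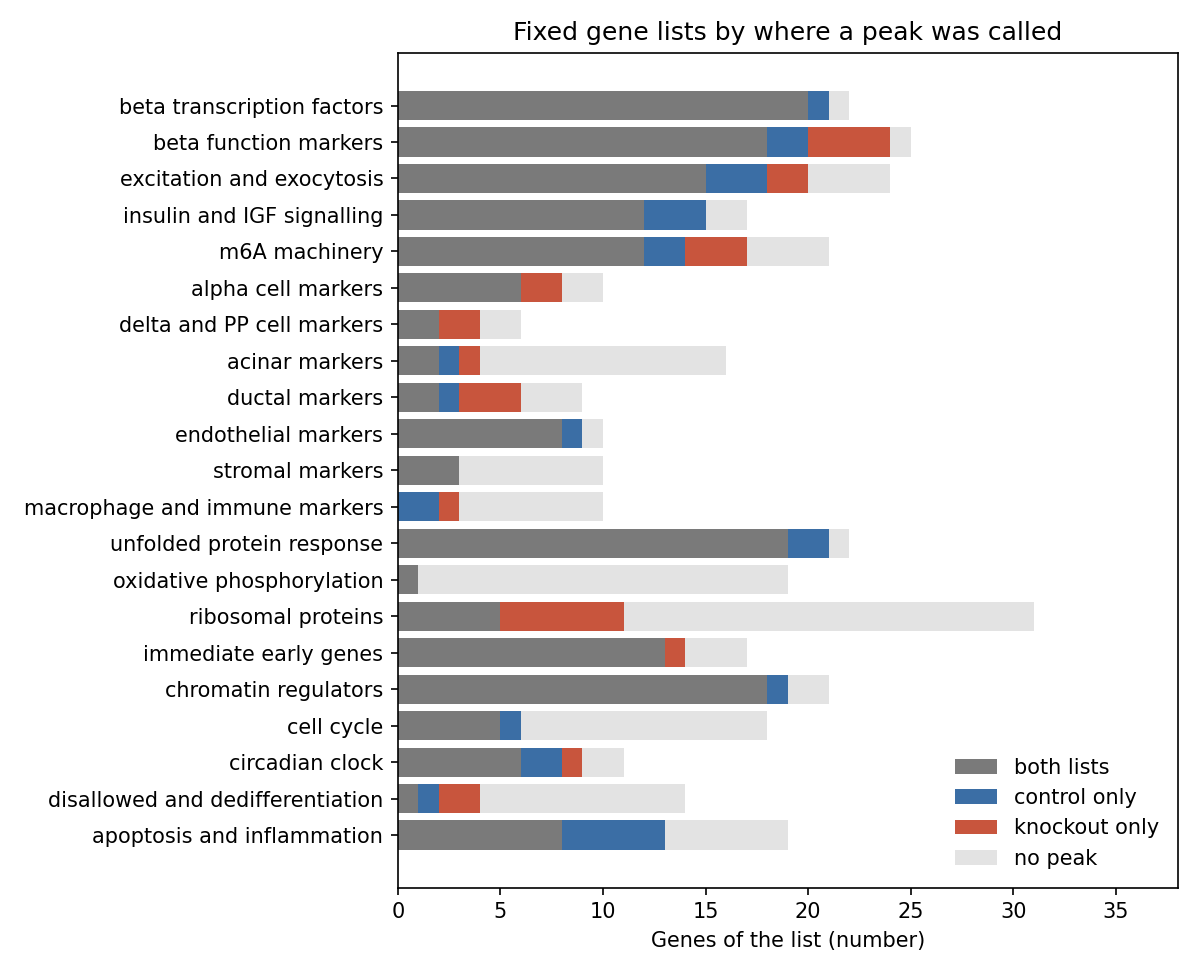
Number of genes (horizontal axis) of each of the 21 gene lists (vertical axis) with a peak in both lists (dark grey), control alone (blue), knockout alone (red) or neither (light grey). Ribosomal proteins have 6 genes with a knockout peak alone and 0 with a control peak alone.

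Peaks that joined exons were more frequent in the knockout list, where 18.0% (17.2 to 18.8) covered more than 1 exon, against 11.7% (11.1 to 12.3) in the control list. The shares of shared peaks were 16.3% (15.3 to 17.2) and 15.5% (14.5 to 16.5). Of unshared peaks, 20.8% (19.5 to 22.2) of knockout peaks and 7.63% (6.93 to 8.38) of control peaks spanned a junction. The unshared knockout share was 33.6% (25.2 to 42.8) in the fifth with the lowest q and 15.6% (13.6 to 17.8) in the fifth with the highest, and the control shares were 8.58% (5.52 to 12.6) and 7.35% (6.15 to 8.70). Within 2000 bp of the 3′ end of the gene lay 39.6% (38.2 to 41.0) of unshared control peaks and 33.7% (32.0 to 35.4) of unshared knockout peaks, against 30.4% and 30.2% of shared peaks. Within 1000 bp the unshared shares were 22.4% (21.2 to 23.6) and 20.6% (19.2 to 22.1), with intervals that overlap.

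**Figure D4:**
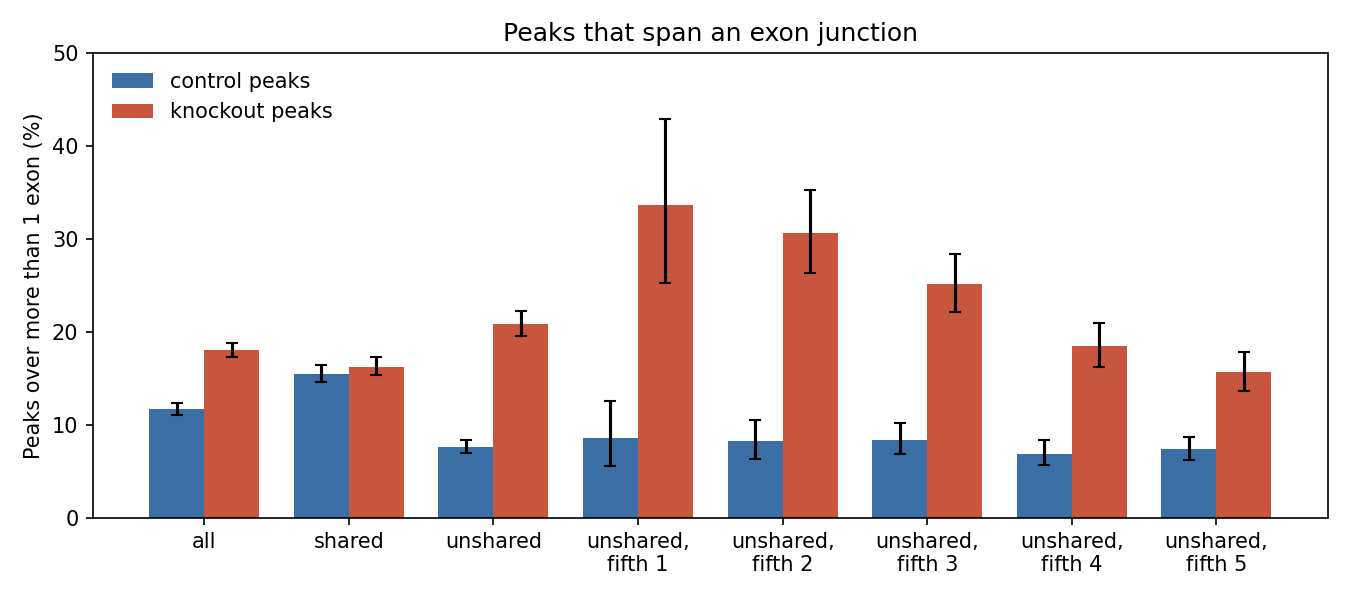
Percent of peaks that cover more than 1 exon (vertical axis) for all, shared and unshared peaks and for unshared peaks in 5 parts by q, in control (blue) and knockout (red), with exact 95% intervals. The bars of shared peaks are 15.5% and 16.3%, and those of unshared peaks are 7.63% and 20.8%.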

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

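Alternatives for the knockout direction, for position, for exon junctions, with q-matched random sets, by q in genes of both lists, without grid peaks and without the beta cell lists were chosen after seeing the data. Of all alternative values, 321 stayed within the tolerance, which was 1.5 times for counts, the 95% interval for shares and, for percentiles of gene lists, the same side of the limits of the random sets. Beyond it, 50 moved, 16 lost and 11 gained a place outside the random sets, and 2 reversed. The cause of these changes was not tested. No paired analysis was possible because each genotype had 1 pool, and leaving out a replicate was not possible for the same reason. The alternatives for transcript regions and motifs were not run. Depth limits peaks with few reads, and read depth is unknown.

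Ordering by −log10 q in place of fold reversed the comparison of peak strength, with the shared peak higher in 77.4% of control and 77.0% of knockout pairs; by fold it was 39.1% and 41.5%, and 44.3% for knockout pairs under a 50% reciprocal overlap. Without peaks on the repeated steps of fold it was 46.3% and 49.0%.

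Control peaks overlapping a knockout peak were 35.5% under a 50% reciprocal overlap, 55.8% within 200 bp, 54.1% at q of 0.001 or less in both lists, 48.4% at a fold of at least 2, 56.4% with equal numbers and 60.7% at q of 0.001 or less in the control list alone. The same shares of knockout peaks were 41.4%, 65.4%, 64.6%, 58.6%, 58.3% and 70.4%. Control-peak genes without a knockout peak were 36.2% at a fold of at least 2, 29.8% with equal numbers and 26.6% at the stricter q in the control list alone, and knockout-peak genes without a control peak were 24.9%, 27.6% and 16.5%. With a window of 1000 bp, 19.4% of control and 18.0% of knockout peaks lay near the 3′ end. Unshared peaks over a junction were 4.43% (control) and 14.4% (knockout) with at least 25 nt on both sides, 8.76% and 17.3% under the reciprocal overlap, and 23.6% in the knockout at the stricter q.

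Shares of peaks in place of genes were 32.7% for beta cell transcription factors, 37.5% for beta cell function, 43.6% for the m6A machinery, 31.7% for chromatin regulators, 35.7% for the 3 beta cell lists and 32.7% for all listed genes. In the better 50% of genes by q, control-only shares were 0.0% for beta cell transcription factors, endothelial, chromatin, cell cycle and apoptosis genes, 100% for ductal markers and 7.55% for all listed genes. At a fold of at least 2 they were 100% for acinar and oxidative phosphorylation genes, 0.0% for cell cycle and 19.6% for all listed genes, and at the stricter q 0.0% for endothelial and 100% for oxidative phosphorylation genes. Knockout-only shares were 100% for delta and PP and for acinar markers at a fold of at least 2, and 0.0% for dedifferentiation genes at the stricter q.

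Control-only percentiles at the stricter q were 17.1 for beta cell transcription factors, 1.38 for endothelial markers and 4.12 for the 3 beta cell lists. In the better 50% by q they were 7.56 for beta cell transcription factors, 9.17 for immediate early genes, 18.6 for the 3 beta cell lists, 44.4 for the 7 other cell types and 7.90 for all listed genes. Without matching they were 0.920 for beta cell function, 0.685 for the unfolded protein response, 0.260 for chromatin and 3.42 for other cell types. With q-matched sets they were 2.05 for ribosomal proteins, 10.9 for immediate early genes, 16.4 for the 3 beta cell lists, 7.90 for other cell types and 3.90 for all listed genes without the 3 beta cell lists, and at a fold of at least 2, 9.18 for immediate early genes and 7.07 for other cell types. Knockout-only percentiles without matching were 2.33 for insulin signalling, 0.295 for the unfolded protein response, 0.395 for chromatin, 0.675 for the 3 beta cell lists and 0.0400 for all listed genes. At the stricter q they were 2.54 for beta cell transcription factors, 96.3 for ribosomal proteins and 1.91 for all listed genes.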

Other observations

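Tests on beta cell transcripts, other cell types, q in genes of both lists, the repeated fold values and peak length were chosen after the result was seen, and the exon junction pattern itself was picked out after 6 features of shared and unshared peaks and 16 families of gene names had been looked at.

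Of 19 named ribosomal protein genes with a peak in either list, chosen after their values were seen, 12 had peaks in both, 7 a knockout peak alone and 0 a control peak alone. Beyond the fixed list were 8 of the 19, of which 7 had peaks in both lists and 1, Rpl24, a knockout peak alone. Named mitochondrial genes with a peak numbered 7 in each list. Genes with olfactory receptor names (Olfr) had 0 peaks in both lists.

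Peaks called in one genotype alone were weighed against low read counts, the calling threshold and a loss centred on beta cell transcripts. Control peaks on the grid of repeated folds, taken as a mark of few input reads, lacked a knockout counterpart in 78.5% of cases (76.3 to 80.5), against 59.7% for other peaks weighted to the same q, so low counts may contribute. Peaks near the threshold stay open, because 12.2% of control peaks in the fifth with the lowest q had no counterpart, which lies between the 5% and 20% set in advance. A loss of all peaks centred on genes of the 3 beta cell lists was not seen, but the test could not decide on it. These lists lay outside the random sets in the main setting and inside them in others. The control-only share of these lists was 10.2%, against a median of 22.0% in matched sets (percentile 0.580). The percentile was 16.4 with q-matched sets, inside their range, and lay between 0.0 and 18.6 over all settings, always on the side of fewer losses. A call of any peak does not show a partial loss in a strongly called gene, so a partial loss centred there stays open. A real loss of m6A in the knockout stays open too, as 1 pool per genotype cannot part it from differences between pools.

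A lower share of beta cell RNA in the knockout pool could give knockout peaks on markers of other cell types. The 7 lists of other cell types together lay at percentile 60.3 of sets matched in the knockout list, and single lists ranged from 4.36 for endothelial to 89.2 for ductal markers. In genes with peaks in both lists, the best −log10 q was lower in the knockout for 6 of 23 such markers (percentile 0.005 of sets matched on control q), with 1 of 2 acinar and 1 of 2 ductal genes, and for 38 of 53 genes of the 3 beta cell lists (percentile 30.4). The m6A machinery, which marks no cell type, also had few lower values, 4 of 12 genes (percentile 1.83), so the shift was not confined to these markers. The number of lists that random sets would put outside was not computed for this count. A lower share of beta cell RNA could give the difference between the markers and the beta cell lists. So could a loss of m6A in beta cells alone, which the design names. These cannot be told apart, because q moves with RNA level as well as with m6A and the calls of knockout peaks alone lay inside the range of the matched sets.

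Knockout peaks without a counterpart spanned exon junctions more often than such control peaks, and 3 explanations were tested. Peak length was argued against, since the control share weighted to knockout peak lengths was 7.67%. Different genes were argued against, since among genes with peaks in both lists the shares were 22.9% (21.1 to 24.7) and 8.80% (7.75 to 9.94). Unshared control peaks lay near 3′ ends more often in these genes (30.9% against 26.1%). This comparison was the first test of fewer knockout calls at 3′ ends, and it went with that explanation. It was replaced, before the stricter test was run, by leaving out peaks within 2000 bp of the 3′ end. The shares over a junction were then 31.0% (28.7 to 33.4) and 11.2% (9.78 to 12.8), which argued against such calls as the whole cause. A change in where m6A is written and a difference between the pools in RNA quality or unspliced RNA were not tested and stay open.

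Fold values repeated, as whole reads over an input with none could give: 86.3% of control folds of 10 or more lay within 0.06 of a multiple of 1.05, where 11.4% is the share that tolerance gives by chance, and 88.3% of knockout folds lay on multiples of 0.816, where chance gives 14.7%.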
